A study of Mus musculus with 8 samples.

How the data were processed

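RNA of cultured mouse primary myoblasts was measured on Affymetrix MoGene 1.0 ST arrays, which carry probe sets for whole transcripts and use a single colour. The 8 arrays are 4 labelled WT and 4 labelled Runx1f/f, each numbered 1 to 4 and called biological replicates in the labels. Per the labels' protocols, satellite cells came from gastrocnemius muscles of C57bl/6 animals aged 2 to 3 weeks, were grown on Matrigel in proliferation medium, and 200 ng of total RNA was labelled per array. The labels also give each sample a source number. In rising order these numbers fall into 3 runs, 139 to 142, 160 to 161, and 181 and 189, whose meaning is not given in the sources used here.

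The deposited table holds log2 intensities, 1 value per probe set and array, and RMA and Partek are named in the submitters' processing notes without versions. RMA corrects the background, quantile-normalizes the arrays together and summarizes the probes of a set on the log2 scale. No label or header records any further adjustment. The deposited log2 values were tested for such a step: in all 35399 rows the mean of the 4 columns labelled WT, the mean of Runx1f/f 1 and 2 and the mean of Runx1f/f 3 and 4 were equal within 7.5e-05. A principal component analysis accordingly found 5 components with variance, where 8 independent arrays give 7 after centring (8 arrays less 1 for the mean), so the residual degrees of freedom used by any test of these columns are overstated. Each column was assigned to its sample by the accession in its header. Array medians were 4.39 to 4.41. No 2 arrays held identical values, and correlations over all rows ran from 0.9879 to 0.9972. The number of arrays limits the precision, and no detection p-values were used here.

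Probe sets were named through the platform annotation provided with the table. Of 23410 annotated rows, 21789 had 1 gene symbol and 1621 had several, and 11989 rows were not annotated there. Gene identifiers of 21698 of the single-symbol rows matched a RefSeq gene table (GRCm38.p6), which changed 0 symbols. Each gene was represented by its probe set with the highest mean over the 8 arrays, which left 19938 genes, 999 of them with more than 1 probe set. No filter on dim probe sets was applied.

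The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Before the data were examined, the design, the alternatives, the 24 gene lists and the rule for the genes named were fixed. The rule takes the 12 largest changes each way past the threshold, or, with fewer than 5 genes passing, the 10 with the smallest p. It adds Runx1, Pax7, Myf5, Myod1, Myog, Jun and the sex-linked genes, and from each list up to 4 passing members or, if none passes, the 2 with the largest absolute difference. Because no gene passed, the last part of the rule picked members by differences that are rounding of the deposited values. Genes named outside it in the closing section were chosen after their values were seen. On simulated arrays with the means and spreads of these 19938 genes and 200 genes changed, this fit recovered 94% and 96% of genes raised or lowered by 1 on the log2 scale and 100% and 98% of those changed by 2, with 14 false calls among 208. The simulated arrays were drawn independently, without the equal means of the deposited column sets. Their recovery therefore does not describe the power of the fit on the deposited columns, and gives no weight to a count of 0 there.

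The same replicate numbers occur in both genotypes, so their pairing was checked before calls were compared. Deviations from the genotype means correlated by 0.39, 0.46, 0.60 and 0.57 for numbers 1 to 4. The numbers were treated as pairs in an alternative fit, but these values do not establish a pairing. WT 4 correlated by 0.64 with Runx1f/f 1, above the 0.57 with its own number. Deviations of Runx1f/f 1 and 2 are mirror images (correlation -1), as are those of 3 and 4, so the values are not independent. The labels give no pairing, and 4 of the 8 arrays correlated best with their own number in the other genotype. Other alternatives were a block for the source number runs, centring or repeated quantile normalization, a filter on dim genes, all probe sets or rows, other variance models and thresholds, and each array left out. A fit within the first run of source numbers was added after seeing the data. The value table was the only data file, and scanner files were not used here.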

Results

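Gene expression was profiled in primary myoblasts, the proliferating cells that grow out of muscle satellite cells in culture. The series asked which genes depend on the transcription factor Runx1 early in muscle regeneration, and compared WT myoblasts with myoblasts from Runx1f/f mice, which the labels also call knockout. Each genotype was represented by 4 arrays. Values are log2 intensities after RMA, given as mean ± SD over the 4 arrays labelled with a genotype, and differences are Runx1f/f minus WT.

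No gene differed between the labelled genotypes. Of 19938 genes, 0 were higher and 0 lower in arrays labelled Runx1f/f (limma, adjusted p under 0.05), and 0 had an unadjusted p under 0.05. The smallest p over all genes was 0.99889. The means of the 2 labelled genotypes were equal in every gene to within 5.25e-05, while the median SD between arrays of a genotype was 0.0911. Differences of that size are rounding of the deposited values. Over genes, the median absolute difference was 9.63e-06 of its ordinary standard error, where 2 groups with no effect give a median near 0.718. The deposited values therefore carry no difference between these column sets, and the tests below do not measure whether Runx1 loss changes expression. The 10 genes with the smallest p were Vim, which encodes vimentin, Psmd1, Ppib, Ndufa10, Srsf2, Psap, Cct5, Bnip2, Selenof and Srsf3. None passed, and the largest difference among them was 5.25e-05, in Bnip2.

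**Figure D1:**
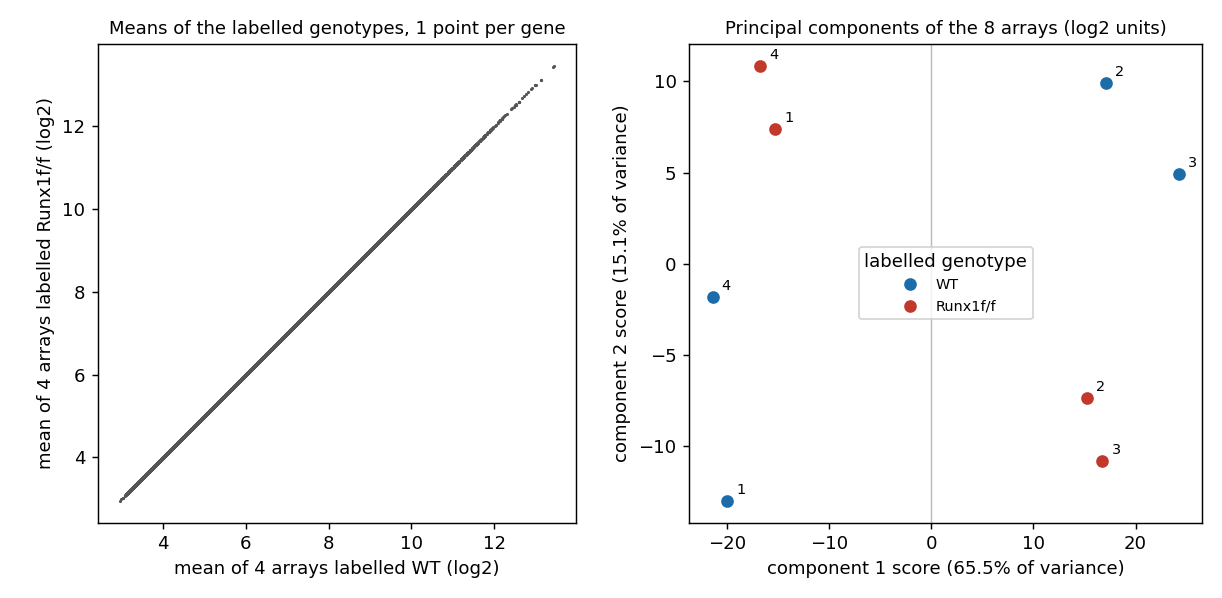
Left, the mean log2 intensity of the 4 arrays labelled Runx1f/f against that of the 4 labelled WT, 1 point per gene for 19938 genes, all on the diagonal. Right, scores of the 8 arrays on the first and second principal components (65.5% and 15.1% of the variance), coloured by labelled genotype and numbered by replicate; numbers 2 and 3 of both genotypes lie on the positive side of component 1, and numbers 1 and 4 on the negative side.

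Runx1, the targeted gene, is represented by 1 probe set. Its level was 9.67 ± 0.55 (SD, n = 4) in arrays labelled WT and 9.67 ± 0.32 (SD, n = 4) in arrays labelled Runx1f/f, and an exact two-sided permutation test over 70 assignments gave p = 1. The equal means of the labelled genotypes fixed that result in advance, so it does not measure an effect on Runx1. The arrays labelled WT read 9.15, 9.99, 10.27 and 9.25 for numbers 1 to 4. Those labelled Runx1f/f read 9.35, 9.98, 9.89 and 9.44. Numbers 2 and 3 were thus above numbers 1 and 4 in both labelled genotypes, and Runx1 did not separate the labels. The deleted part of Runx1 and its overlap with the probe set are not given in the sources used here, so a probe set lying outside it would check nothing.

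Among 19 measured myogenic regulators, 0 were higher and 0 lower in arrays labelled Runx1f/f, also when adjusted over the list alone. Pax7, the satellite cell marker, was at 7.07 ± 0.16 in WT and 7.07 ± 0.09 in Runx1f/f arrays. Myf5 and Myod1, which specify the myogenic lineage, were at 8.11 ± 0.59 and 11.35 ± 0.20 in WT and at 8.11 ± 0.49 and 11.35 ± 0.11 in Runx1f/f arrays. Myog, which drives terminal differentiation, was at 11.34 ± 0.46 and 11.34 ± 0.50. Its 8 arrays ranged from 10.74 in Runx1f/f 1 to 11.94 in Runx1f/f 2. Id3, an inhibitor of basic helix-loop-helix factors, was at 10.46 ± 0.33 and 10.46 ± 0.16, and Met, the receptor for hepatocyte growth factor, at 9.35 ± 0.21 and 9.35 ± 0.22. In the list of 26 satellite cell and Notch genes, 0 passed. Its named members, the integrin Itga7 and the syndecan Sdc4, were at 10.21 ± 0.10 and 10.27 ± 0.28 in WT and 10.21 ± 0.20 and 10.27 ± 0.30 in Runx1f/f arrays.

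**Figure D2:**
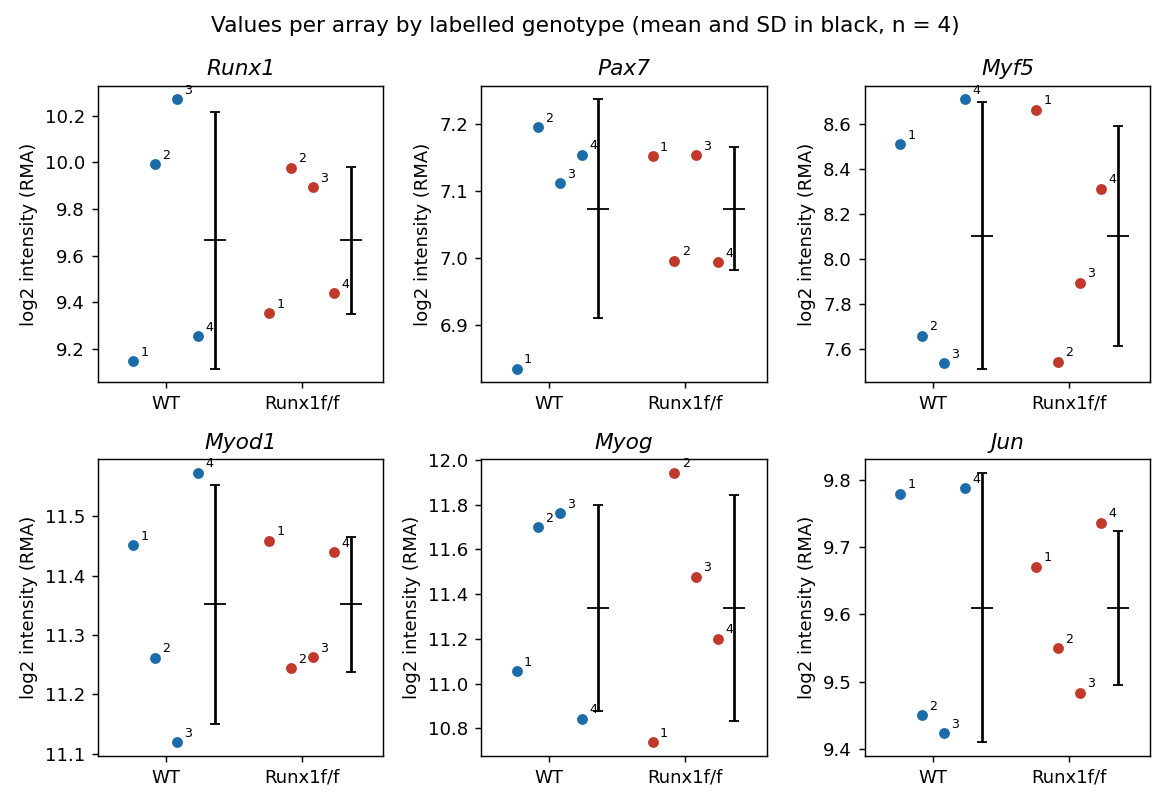
Log2 intensity (vertical axis) of Runx1, Pax7, Myf5, Myod1, Myog and Jun in each array, by labelled genotype (horizontal axis); coloured points are arrays numbered by replicate, and black bars show mean and SD (n = 4). The genotype means coincide in each panel, and for Runx1 numbers 2 and 3 lie above numbers 1 and 4 in both genotypes.

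The contractile genes showed 0 members higher and 0 lower among 47 measured. Actn2, a Z-disc actinin, was at 10.73 ± 0.42 in WT and 10.73 ± 0.79 in Runx1f/f arrays, and the actin Actc1 at 13.00 ± 0.20 and 13.00 ± 0.36. The median of the list differed between arrays, from 9.26 to 10.20. For excitation-contraction coupling, muscle energy and fusion genes, 0 of 30 passed. There the acetylcholine receptor subunit Chrng was at 11.22 ± 0.05 and 11.22 ± 0.19, and the fusion protein gene Mymk at 11.55 ± 0.14 and 11.55 ± 0.23.

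Cell cycle genes were also equal between the labels, which the equal means fix for every gene. Of 33 G2/M genes, 33 S phase genes and 20 inhibitors and G1 regulators, 0 passed in each list. Anln and Cenpa, needed in cytokinesis and at centromeres, were at 8.84 ± 0.12 and 8.03 ± 0.17 in WT and at 8.84 ± 0.17 and 8.03 ± 0.11 in Runx1f/f arrays. The replication genes Rrm1 and Pcna were at 10.57 ± 0.24 and 10.15 ± 0.30 in WT and at 10.57 ± 0.24 and 10.15 ± 0.12 in Runx1f/f arrays. Cdk4 was at 11.75 ± 0.08 and 11.75 ± 0.05, and the stress gene Gadd45a at 10.48 ± 0.03 and 10.48 ± 0.23.

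The series title names MyoD and c-Jun as partners of Runx1. Jun, which encodes c-Jun, was at 9.61 ± 0.20 in WT and 9.61 ± 0.11 in Runx1f/f arrays, and 0 of 13 AP-1 family members passed. Fosb was at 4.13 ± 0.05 and 4.13 ± 0.13, and Fos at 4.57 ± 0.30 and 4.57 ± 0.03. Of 15 Runx family members and partners, 0 passed, with Cbfa2t2 at 7.67 ± 0.20 and 7.67 ± 0.10.

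Signalling and matrix lists gave 0 passing members among 38 extracellular matrix, 39 growth factor, 23 cytokine and 21 interferon response genes. The widest spread among the named members was in Thbs1, the matrix protein thrombospondin, at 10.34 ± 1.22 in WT and 10.34 ± 0.67 in Runx1f/f arrays. Sparc was at 11.14 ± 0.08 and 11.14 ± 0.17. The macrophage growth factor Csf1 was at 8.74 ± 0.58 and 8.74 ± 0.09, Ccl9 at 3.68 ± 0.04 and 3.68 ± 0.07, Cxcl10 at 3.88 ± 0.17 and 3.88 ± 0.31, and Ddx58 at 4.04 ± 0.02 and 4.04 ± 0.13. Fgfr2 was at 3.83 ± 0.03 and 3.83 ± 0.05, and Igf1 at 4.57 ± 0.13 and 4.57 ± 0.29.

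Metabolic and stress lists likewise had 0 passing members, among 18 hypoxia and glycolysis, 16 cholesterol synthesis, 19 unfolded protein and oxidative stress, and 16 p53 target genes. The glycolytic genes Pgk1 and Pkm were at 11.76 ± 0.02 and 11.43 ± 0.08 in WT and 11.76 ± 0.04 and 11.43 ± 0.08 in Runx1f/f arrays. Insig1 and Hmgcs1, of sterol metabolism, were at 10.40 ± 0.38 and 9.89 ± 0.18 in WT and at 10.40 ± 0.30 and 9.89 ± 0.23 in Runx1f/f arrays. Hsph1 was at 10.51 ± 0.06 and 10.51 ± 0.08, Txnrd1 at 10.14 ± 0.14 and 10.14 ± 0.05, Eda2r at 9.09 ± 0.28 and 9.09 ± 0.20, and Pmaip1 at 5.79 ± 0.56 and 5.79 ± 0.23.

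Markers of other cells that a muscle culture can hold were equal between the labels as well. The equal means fix this for every gene, so it does not show that the cultures held the same mix of cells. Among 17 fibroblast and fibro-adipogenic, 21 leukocyte, 15 endothelial, 13 pericyte and smooth muscle, 11 adipocyte and 9 Schwann cell and neural markers, 0 passed in each list. Col1a1 was at 4.62 ± 0.15 and 4.62 ± 0.21 and Dcn at 3.50 ± 0.05 and 3.50 ± 0.07. The complement genes C1qa and C1qb, of macrophages, were at 3.32 ± 0.03 and 3.28 ± 0.04 in WT and 3.32 ± 0.04 and 3.28 ± 0.05 in Runx1f/f arrays. Endothelial Cdh5 and Cldn5 were at 3.51 ± 0.05 and 3.57 ± 0.06 in WT and 3.51 ± 0.03 and 3.57 ± 0.03 in Runx1f/f arrays. Tagln was at 6.33 ± 0.72 and 6.33 ± 0.21, Cnn1 at 3.57 ± 0.07 and 3.57 ± 0.06, Fabp4 at 3.87 ± 0.03 and 3.87 ± 0.09, Gfap at 3.36 ± 0.13 and 3.36 ± 0.05, and Tubb3 at 3.63 ± 0.36 and 3.63 ± 0.05. The fatty acid transporter Cd36 had the widest spread among the named genes in Runx1f/f arrays, at 7.30 ± 1.17 in WT and 7.30 ± 1.59 in Runx1f/f arrays. Of 4 sex-linked genes, 0 passed. Xist, expressed from the inactive X, read between 9.37 and 9.71 on all 8 arrays. The Y-linked genes Kdm5d, Eif2s3y and Uty were at 3.51 ± 0.04, 3.50 ± 0.08 and 3.52 ± 0.16 in WT and at 3.51 ± 0.03, 3.50 ± 0.03 and 3.52 ± 0.08 in Runx1f/f arrays.

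Over the 24 lists, camera called 0, with a smallest adjusted p of 0.0985 for hypoxia and glycolysis and of 0.999 with an estimated correlation, and the smallest fry p was 0.9999. Camera sets a list against the spread over all genes, which here is rounding, so its p-values describe rounding only.

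Because the genotype means are equal, differences within the runs of source numbers, weighted by their arrays, must cancel for every gene, so opposite signs between runs are fixed. Runx1 was 0.10 higher in Runx1f/f arrays in the run 139 to 142 (2 arrays per genotype). The difference was -0.38 in the run 160 to 161, and Runx1 was 0.19 higher in the run 181 and 189, each with 1 array per genotype and no test. Myf5 differed by 0.02, 0.36 and -0.40 in the same order, and Myog by -0.04, -0.28 and 0.36. In the first run, limma called 0 genes, and 11 had an unadjusted p under 0.05, far fewer than the 5% of genes that independent values without an effect give.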

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

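The check for an array far from the others of its labelled genotype was run on 178 groups of 4 values, the named genes and the list medians, and marked 1. In 65 of these groups, the Runx1f/f values of single genes, the equal means of arrays 1 and 2 and of arrays 3 and 4 make the values symmetric, which rules out a mark. Among the other 113 groups, chance marks about 5% of groups of independent values. Srsf2, which encodes a splicing factor, read 11.69 in WT 4, against 11.58 in the nearest and 11.56 in the farthest of the other WT arrays.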

How the results depend on the processing

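The counts of 0 genes higher and 0 lower held under each alternative setting run: the blocks, scalings, the dim filter, all probe sets or rows, both variance models, the 3 other thresholds and each array left out. Settings that keep all columns, unscaled and equally weighted, keep the equal means, which fixed their counts in advance. Their agreement says nothing about robustness. With the replicate number as a block, the counts stayed at 0 and the Runx1 difference at -1.25e-05, and the block changed no other call. Leaving out 1 array breaks the equality of the means, and the Runx1 difference then ran from -0.17 without WT 1 to 0.20 without WT 3. To rounding, such a difference is set only by the deviation of the left-out array from its genotype mean. These fits therefore do not compare the genotypes, and their counts of 0 say nothing about robustness either. With 1 array left out, 0 to 27 genes had an unadjusted p under 0.05, far below the 5% of 19938 genes that independent values without an effect give. The number of lists called by camera, 0 in the main fit, became 18 with arrays centred on their medians, 3 with quantile normalization applied again, 6 with array weights, and 1 with all probe sets of 1 symbol and 1 with all rows. With 1 array left out it ranged from 0 (without WT 2) to 7 (without Runx1f/f 1 or Runx1f/f 2), being 4 without WT 1, WT 4, Runx1f/f 3 or Runx1f/f 4 and 5 without WT 3. Within the first source number run, an alternative chosen after seeing the data, it was 4. With an estimated correlation, 2 lists were called after centring, 1 without WT 1 and 0 in the other fits. By its construction camera scales to the spread over genes, and after centring the largest difference of a named gene was 0.00448, far below the array spread. With array weights it was 0.10, in Cd36. With 1 array left out it was 0.29 to 0.47, in Thbs1 or Cd36, and within the first run 0.47, in Pmaip1. These values exceed the median array spread over genes. The SDs in WT and Runx1f/f arrays were larger for Cd36 (1.17 and 1.59) and Thbs1 (1.22 and 0.67). For Pmaip1 they were 0.56 and 0.23. With 1 array left out, the list calls reflect the deviation of that array and not the labelled genotype. The cause of the other list calls was not tested. Signal over background could not be used as a limit, because detection values were not analysed here.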

Other observations

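All tests in this part were chosen after the values had been seen. The arrays differed from one another along a leading principal component that held 65.5% of the variance and crossed the labelled genotypes, with WT 2, WT 3, Runx1f/f 2 and Runx1f/f 3 on the positive side. A gene's span is its fitted log2 change from the lowest-scoring to the highest-scoring array. Of 19938 genes, 626 spanned more than 1.5-fold upward and 307 more than 1.5-fold downward. The 12 genes with the widest upward spans were taken without predicted genes and genes named only by clone identifiers, such as AW551984 with 4.75. Of these 12, 4 are known as imprinted (Dlk1, Cdkn1c, Rian and Meg3), and imprinted genes were not tested as a list. Dlk1, a Notch-like ligand, read 4.28, 8.61, 9.52 and 4.11 in WT 1 to 4 and 4.72, 8.55, 9.55 and 3.71 in Runx1f/f 1 to 4. Cdkn1c, the cell cycle inhibitor p57, read 6.10, 11.05, 11.36 and 6.56 in WT and 7.25, 10.29, 10.17 and 7.37 in Runx1f/f arrays. The noncoding RNAs Meg3 and Rian spanned 3.12 and 4.86. In the opposite direction lay Sp7, an osteoblast transcription factor, with a span of -3.39, the growth factor binding protein Igfbp2 with -3.27, the protease Mcpt8 with -3.20 and the lipoxygenase Alox5 with -2.88.

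Muscle genes moved along this component as well. In the contractile list, 27 of 47 members spanned over 1.5-fold upward and 1 downward, among them Mybpc1 with 1.83, Myoz2 with 1.62 and Myh8 with 1.40. The coupling and energy list had 13 of 30 upward and 0 downward, with Cav3 at 1.44 and Ckm, muscle creatine kinase, at 1.21. Of the 19 myogenic regulators, 4 spanned over 1.5-fold upward and 1 downward, and their median span was -0.09. Among them Mef2c spanned 1.52 and Myog 0.92, whereas Myf5 spanned -1.10, Myf6 -0.41 and Myod1 -0.33. Runx1 spanned 0.94. Replication genes leaned downward, with a median span of -0.37 for the S phase list and -0.19 for the G2/M list, and Rrm2 at -0.68. These spans describe the 8 arrays without regard to genotype. No correlation between genes over arrays is given, because the arrays form 2 clusters of 4.

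The equal means of the labelled genotypes were the first pattern weighed. Unadjusted values of genotypes with the same expression are excluded, since the median difference was 9.63e-06 of its standard error. An adjustment that set the means of 3 column sets equal, as a batch correction does, is a candidate explanation without an independent test: of the 210 ways to part 8 columns into sets of 4, 2 and 2, 1 had equal means in every row, namely the 4 WT columns, Runx1f/f 1 and 2, and Runx1f/f 3 and 4, which restates the observation. With columns and labels as deposited, an adjustment over the runs of source numbers is excluded, because run means differed by up to 5.62. Whatever made them equal, means that agree to rounding give no measure of an effect of the labelled genotype. With a real count of 0 genes, all 35 of 35 splits of the arrays give at least as many whatever the data, so the count of splits says nothing about chance. The highest other split, with WT 1, WT 4, Runx1f/f 1 and Runx1f/f 4 on one side, gave 2945 genes, the next 12, and 29 splits gave 0. Among the 8 splits that part all 4 replicate pairs, the highest other gave 12. A count so far above the rest points to a structure of the samples that the labels, as attached to the columns, do not describe.

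The second pattern was the spread of both labelled genotypes along the leading component. A candidate explanation is that the value columns stand in the order of the source numbers while the samples are listed by genotype. Read in source number order, the columns would put the equal-mean sets on the runs 139 to 142, 160 to 161, and 181 and 189, which were written down before the data were examined, and 8 of 8 arrays would fall on the side of their genotype. The split with 2945 genes is then the split by genotype. It is also the split of the arrays by side of the component, so it gives no support separate from the 8 of 8 arrays. Equal means within the sets leave 28 possible sign patterns, so the match of 8 of 8 arrays alone is 1 of 28. The targeted gene gives this reading no support from a lower level: Runx1 read 9.89 to 10.27 on the positive side, which would be the Runx1f/f arrays, and 9.15 to 9.44 on the other, and the deleted part of the gene is not known here. Without the original scanner files this stays a hypothesis, and no array was reassigned in any test. Different progress into muscle differentiation is a candidate for the same component, and both explanations may hold together. The contractile list's median span of 0.66 lay at the 100th percentile of 10000 random lists matched on mean level. These lists were not matched on spread, and the contractile list's median SD was 0.42, against 0.0911 over all genes. A high percentile therefore cannot single out differentiation. The measure is not particular to muscle, since 9 of the 24 lists lay in the outer 5% of their random lists, the interferon response (99.43) and p53 target (1.40) lists among them. Different shares of fibroblasts, leukocytes or endothelial cells stay open: 1 of 15 abundant markers spanned over 1.5-fold, Laptm5 with -0.96, but 11 of the 15 stayed below the array medians on all arrays, too dim to exclude a change. The fibroblast list had a median span of 0.09, at the 99.98 percentile of its random lists. Of its 17 members, 2 spanned over 1.5-fold upward, Islr with 0.75 and Gsn with 0.70, and 0 downward. Dpep1 and Thy1 leaned downward, with -0.38 and -0.24. Among the abundant fibroblast markers, Col1a2 spanned -0.37 and Col3a1 0.17.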
